A study of Mus musculus with 6 samples.

How the data were processed

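RNA was measured by sequencing in adipocytes that were grown and differentiated in culture from the stromal-vascular cells of 3 mouse fat depots: epididymal white fat (eWAT), inguinal white fat (iWAT) and brown fat (BAT). Per the labels, the cells came from male NMRI mice aged 4 to 5 weeks, and the BAT cells were pooled from the interscapular, cervical and axillary depots. The stromal-vascular fraction is the mixture of cells released from fat by collagenase once the mature adipocytes are removed. Per the labels, the cultures received medium with 10% newborn calf serum, 30 nM insulin and 1 µM rosiglitazone, a drug that activates the adipogenic regulator Pparg. They were harvested 8 days after plating, although the count table tags its samples with day 7, and only those in which more than 50% of the cells had differentiated were used. Total RNA was extracted with TRIzol, depleted of ribosomal RNA and made into libraries with a TruSeq kit. The labels state neither the strandedness of the libraries nor that the replicates of a depot came from separate animals or cultures.

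Per the labels, the authors aligned the reads with STAR to the mouse genome build mm9. The versions, the program that counted reads and the handling of reads that fit several places are not given in the sources used here. The deposited count table holds a whole-number read count per gene and library, and per the file headers no normalization was applied to it. A further deposited table holds a log2 fold change, a raw p-value and an adjusted p-value for each pair of depots, with the tool not stated beyond a column name for a likelihood ratio. It also holds a deposited log2 value per gene and library, whose correlation across genes with the log2 CPM computed here (CPM, read counts per library scaled to a common total) was 1 in each library. The adjusted p-values deposited by the authors equalled a Benjamini-Hochberg correction of the deposited p-values to within 2.5e-15. All tests in the report started from the count table, and the table of the authors' own tests was used only for comparison.

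The count table had 20295 genes, each with a RefSeq identifier, mm9 coordinates and a symbol, and no symbol repeated. Of these, 2596 had a count of 0 in every library. The filter on low counts (filterByExpr in edgeR, with the depots as groups) left out 8563 genes and kept 11732, which held from 99.73% to 99.81% of each library's counts. Total counts per library ran from 2889038 to 4807449. At those depths a count of 3, taken as the limit that a count of 0 allows, equalled from 0.634 to 1.15 CPM. Where all libraries of a depot were at 0, the fold change was computed against 3 counts over that depot and is given as a lower bound. Where a depot had 1 to 3 counts, the ratio of CPM is given with an exact 95% binomial interval. Such intervals and bounds cover counting error only, not the spread between cultures. Between libraries of a depot the spread was far above counting error: chi-square per degree of freedom over genes with at least 10 counts was 20.4 for BAT, 19.2 for eWAT and 16.7 for iWAT.

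CPM values were scaled with trimmed-mean (TMM) factors, which ran from 0.907 to 1.05, over the counts of the tested genes. The test was the edgeR quasi-likelihood F test, two-sided, on 1 fit of all 6 libraries with the depot as the only term, and p-values were adjusted by Benjamini-Hochberg over the 11732 genes of each contrast. The common biological coefficient of variation was 0.251, with 3 residual and 3.34 prior degrees of freedom. A gene was called at an adjusted p below 0.05. Standard errors of log2 fold changes are the absolute log2 fold change divided by the square root of the F statistic. Genes called highest in a depot were those called higher in it in both of its contrasts. As those contrasts share libraries, the count is given beside that of independent lists and beside the mean of 50 simulated data sets with no depot effect. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The groups, the tests, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined.

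The rule named, for each contrast and direction, the 10 called genes with the largest absolute log2 fold change. These had to have both libraries of the higher depot above both of the lower one and a mean of at least 5 CPM in the higher depot, and symbols of clones, predicted genes and small RNAs were left out. It also named 18 anchor genes whatever their result (Ucp1, Cidea, Ppargc1a, Prdm16, Zic1, Lhx8, Tbx1, Tbx15, Shox2, Wt1, Tcf21, Hoxc9, Hoxc10, Lep, Retn, Adipoq, Fabp4 and Pparg), up to 4 members per gene list and contrast by smallest adjusted p, and the 10 most depot-selective genes. For the contrast of iWAT with eWAT, where the edgeR fit described above called no gene, the same rule was applied to the DESeq2 calls after that count was seen. Other genes were named outside it after their values were seen: Adrb3, Thy1 and Nrg4 for BAT with eWAT, Col6a1, Col6a2 and Col6a3 for BAT with iWAT, and Csf1r, Cox7a1 and Osr1 for iWAT with eWAT. So were Cib2, Mroh6, Cpxm1, Sned1, Sgk2 and Ngfr, which spell out small counts, Lck, Elf3, Epor and Upk3b, and the single genes Lyz2, Gpnmb, Mmp12, Marco and Ctsk among the macrophage genes.

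There were 33 gene lists, written from general knowledge of fat biology, of which 30 had at least 4 tested members. They covered the brown thermogenic programme, brown lineage, beige and white adipocyte markers, the adipocyte differentiation core, de novo lipogenesis, fatty acid oxidation, nuclear-encoded oxidative phosphorylation, the tricarboxylic acid cycle and branched-chain amino acid breakdown. Others covered Hox genes of paralogue groups 1 to 5 and 6 to 13, other patterning regulators, extracellular matrix, the BMP and TGF-beta pathway, the Wnt pathway, complement, cytokines and acute phase proteins, the interferon response, retinoid metabolism, adipokines, the cell cycle, and immediate early and heat shock genes. Cell type lists covered preadipocytes and fibroblasts, smooth muscle and pericytes, mesothelium, skeletal muscle, macrophages, lymphocytes, endothelium, Schwann cells, epithelium and erythroid cells. All members were found in the count table except 1 of 12 mesothelial and 1 of 8 erythroid genes. Lists were tested with camera on the counts and dispersions of the edgeR fit, which camera turns into z-scores. The preset correlation was 0.01, and p-values were adjusted by Benjamini-Hochberg over the 30 lists of a contrast. Camera compares a list with all other genes. Camera with an estimated correlation was run beside it, and so was fry. Fry asks whether the genes of a list move on balance one way, or in its mixed form in either direction, without reference to other genes. Member calls are also counted with the adjustment over the list alone. Principal components were computed from the log2 CPM (prior count 2) of the 1000 most variable genes.

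The tools were tested on simulated counts with the means and spread of these data, 2 libraries per group and 200 changed genes among 11560. In the simulated contrast of BAT with eWAT, edgeR recovered 8.96% of genes changed 2-fold, 64.2% of those changed 4-fold and 86.4% of those changed 8-fold, with 9 false calls among 115. In that of BAT with iWAT it recovered 10.4%, 61.2% and 89.4%, with 12 false among 119. In the simulated contrast of iWAT with eWAT, where nothing was changed, edgeR made 1 false call, DESeq2 15 and limma voom 1. DESeq2 made 27 false calls among 149 for BAT with eWAT, and limma voom 9 among 115. For a simulated shift of 1 list, camera gave an adjusted p of 9.55e-32 at the preset correlation and 0.0269 with an estimated one, with 0 of the other lists called. The simulated genes varied independently, so that 0 does not cover lists whose members vary together. In the real data the estimated correlation of the oxidative phosphorylation list was 0.682 for BAT minus eWAT.

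The alternatives were median-of-ratios and upper-quartile scaling, no filter and a stricter filter (1 CPM in at least 2 libraries), DESeq2, limma voom, an adjusted p below 0.01, a minimum change of 2-fold, a fit of only the 2 depots compared, a term for the replicate number, and leaving out each library in turn. An alternative without Scd1, the gene with the most counts in every library, was added after seeing the data. Gene lengths, used to remove length trends in the closing section, are the counted lengths in the count table. Reads, alignments, sequence variants and transcript isoforms were not analysed here.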

Results

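The data are RNA sequencing counts from 6 cultures of adipocytes differentiated from the stromal-vascular cells of 3 mouse fat depots, with 2 replicates each from BAT, eWAT and iWAT. The total counts of replicates 1 and 2 were 4807449 and 2889038 in BAT, 4094340 and 3363453 in eWAT, and 4244019 and 3857918 in iWAT. From 14149 to 15660 genes had at least 1 count in a library. Scd1, a fatty acid desaturase of lipogenic cells, was the most abundant gene in every library and took from 3.8% to 9.03% of the counts. The replicates are not stated to come from separate animals, so every p-value measures only the spread between these samples, which may be technical.

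On the first principal component, which held 59.6% of the variance of the 1000 most variable genes, the BAT libraries lay at -23.8 and -51.54, the iWAT libraries at 3.305 and -11.06, and the eWAT libraries at 47.28 and 35.81. The second component, with 20.1%, set the iWAT libraries (19.4 and 33.44) apart from the other depots, whose values ran from -19.49 to -4.296. Across genes, which are not independent replicates, the correlation of log2 CPM between replicates was 0.95 in BAT, 0.95 in eWAT and 0.958 in iWAT.

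**Figure D1:**
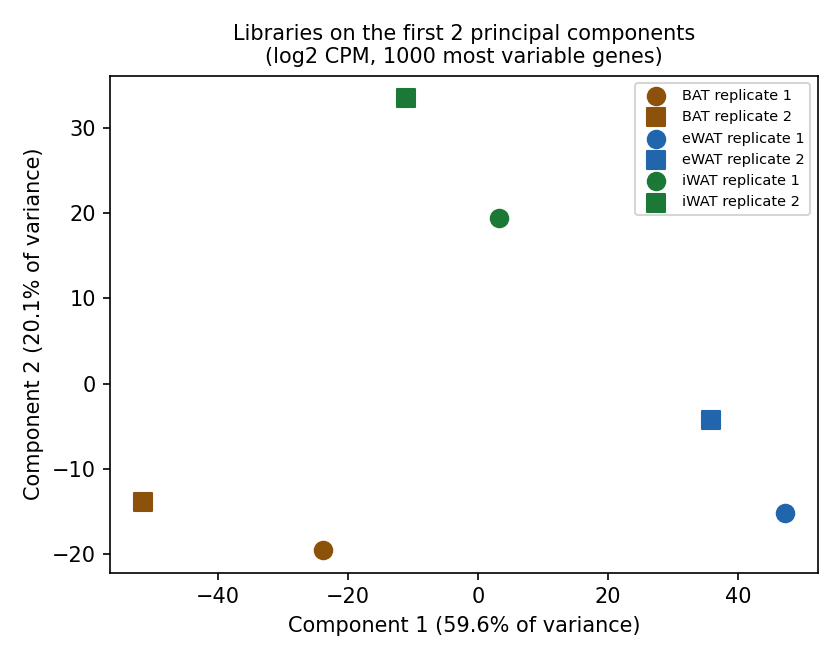
Principal components of log2 CPM over the 1000 most variable genes, with PC1 (59.6% of variance) on the x axis and PC2 (20.1%) on the y axis, each point 1 library. The BAT libraries lie at the lowest PC1 values (-23.8 and -51.54), the eWAT libraries at the highest (47.28 and 35.81), and the iWAT libraries at the highest PC2 values (19.4 and 33.44).

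All cultures expressed genes of the differentiated adipocyte at high levels. Fabp4, the fatty acid binding protein of adipocytes, averaged 28758 ± 4874 CPM (SD, n = 2, as for all CPM values here) in BAT, 16245 ± 507 in eWAT and 17974 ± 1442 in iWAT. Adipoq, which encodes adiponectin, averaged 1817 ± 500.4 CPM in BAT, 1898 ± 704 in eWAT and 1515 ± 123 in iWAT. Pparg, the nuclear receptor that drives adipogenesis, averaged 462.8 ± 96.6, 215.7 ± 67.8 and 287.5 ± 31.0 CPM in the same order. By edgeR with the low-count filter and depot as the only term, none of these 3 genes passed in any contrast. DESeq2 called Fabp4 (adjusted p = 0.00429) and Pparg higher in BAT than in eWAT, as did edgeR with no filter for Pparg. Among 32 tested genes of the adipocyte differentiation core, 2 were higher and 1 was lower in BAT than in eWAT, and 0 passed in the other contrasts. With the adjustment over the list alone, 3 were higher and 2 lower in BAT than in eWAT, 1 higher and 1 lower in BAT than in iWAT, and 0 differed between iWAT and eWAT. The median log2 difference of the list was 0.01 for BAT minus eWAT, 0.13 for BAT minus iWAT and -0.02 for iWAT minus eWAT, and its camera adjusted p was 0.204, 0.218 and 0.684. The leptin gene Lep (3, 2 and 1 counts in BAT, eWAT and iWAT) and the regulator Tbx1 (1, 0 and 0 counts) had too few counts to be tested.

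**Figure D2:**
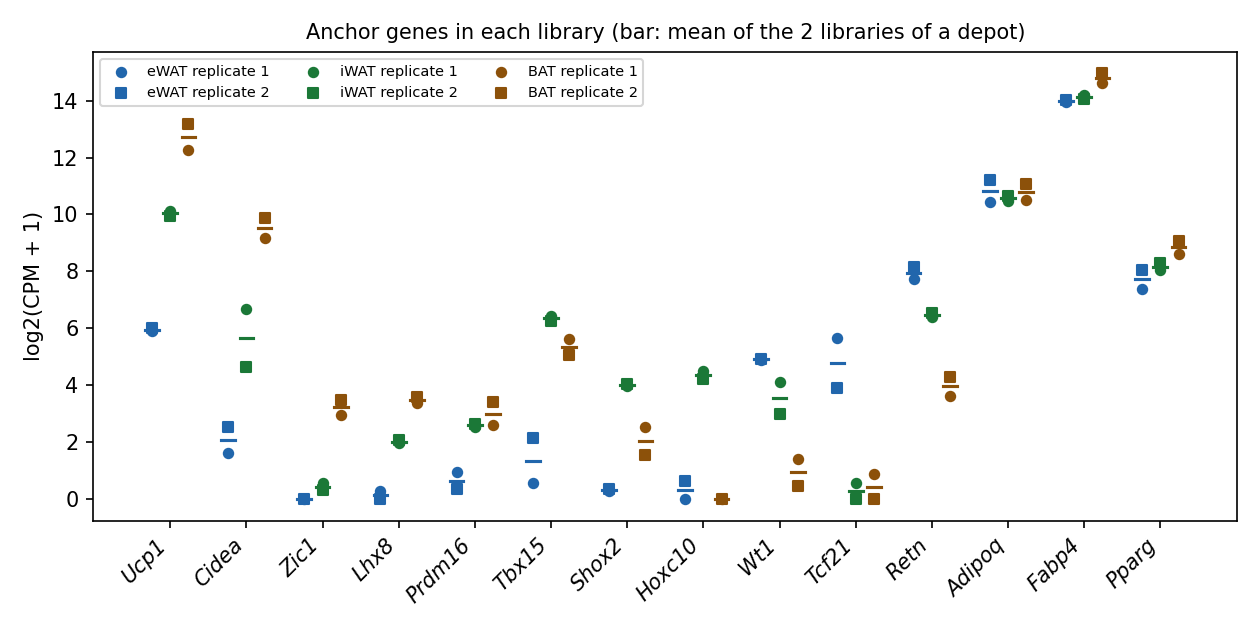
Level of 14 anchor genes as log2(CPM + 1) on the y axis, with each library as a point (circles for replicate 1, squares for replicate 2), depots by colour and bars at the mean of the 2 libraries. Ucp1 averages 7109 CPM in BAT, 1055 in iWAT and 61.25 in eWAT, while Adipoq averages 1817, 1515 and 1898.

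The first contrast asked how adipocytes from brown fat differ from those of epididymal white fat. Ucp1, the uncoupling protein through which brown fat makes heat, averaged 7109 ± 3090 CPM in BAT and 61.25 ± 2.28 in eWAT cultures, a log2 difference of 6.86 ± 0.43 (SE; adjusted p = 0.00657). Cidea, a lipid droplet protein abundant in brown fat, averaged 756 ± 246 against 3.466 ± 1.94 CPM and was higher by 7.79 ± 0.90 (adjusted p = 0.0166). Zic1, a transcription factor gene that marks brown fat, averaged 8.543 ± 2.52 CPM in BAT and had no counts in eWAT, so it was at least 22.2-fold higher (adjusted p = 0.0237). The homeobox gene Lhx8, also a brown lineage marker, had a ratio of 78.7 (counting interval 13.7 to 3148; adjusted p = 0.0167). Tmem45b, which encodes a membrane protein, averaged 341.9 ± 46.9 against 8.395 ± 1.00 CPM, a log2 difference of 5.35 ± 0.22 (adjusted p = 0.00193, the smallest of the contrast). In mm9, these genes are Ucp1 (NM_009463, chromosome 8, 85814247 to 85822355), Cidea (NM_007702, chromosome 18, 67503218 to 67527448), Zic1 (NM_009573, chromosome 9, 91255183 to 91260637), Lhx8 (NM_010713, chromosome 3, 153969258 to 153993524) and Tmem45b (NM_144936, chromosome 9, 31233781 to 31271823).

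Of the 25 tested genes of the brown thermogenic programme, 15 were higher and 1 was lower in BAT than in eWAT, or 19 and 2 with the adjustment over the list alone (median log2 difference 1.95, camera adjusted p = 6.33e-19; adjusted p = 0.281 with an estimated correlation). Besides Ucp1 and Cidea, these included the respiratory chain subunit gene Cox7a1 (2.84), the fatty acid binding protein gene Fabp3 (2.15), Prdm16, a coregulator of brown fat identity (3.43, and from 2.90 to 4.50 with a library left out), and Ebf2, a transcription factor gene of brown preadipocytes (1.82). The member that fell was the adrenergic receptor gene Adrb3 (-0.94, adjusted p = 0.0362). Ppargc1a, the coactivator of mitochondrial biogenesis, averaged 118.6 ± 84.3 CPM in BAT and 39.9 ± 19.2 in eWAT (adjusted p = 0.188). It passed with no filter on low counts, and its log2 difference ran from 0.57 without BAT replicate 2 to 2.17 without BAT replicate 1. Among 8 brown lineage markers, 3 were higher in BAT and 0 lower, also with the adjustment over the list alone (median 1.82, camera adjusted p = 3.68e-06; adjusted p = 0.281 with an estimated correlation). The third of these was Ebf3 (1.91 ± 0.24, adjusted p = 0.0203). The other largest differences in favour of BAT were the kinase gene Sgk2 (5.00), S100b (4.94), the limb and trunk regulator Tbx15 (4.45), the potassium channel gene Kcnc2 (4.21) and Mmd2 (4.12), with adjusted p from 0.0217 to 0.0436. Sgk2 averaged 21.1 ± 0.642 against 0.582 ± 0.824 CPM, with 5 and 0 counts in the eWAT libraries, and its difference was 4.15 without eWAT replicate 2. That of Tbx15 (40.45 ± 11.2 against 1.939 ± 2.08 CPM) was 3.57 without eWAT replicate 1 and 6.36 without eWAT replicate 2. With a library left out S100b ran from 4.24 to 6.05, Kcnc2 from 3.58 to 5.01 and Mmd2 from 3.08 to 4.81. Shox2, a homeobox gene of limb patterning, had a ratio of 14.9 (counting interval 3.752 to 128.9; adjusted p = 0.0416).

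By camera at the preset correlation, genes of mitochondrial energy metabolism were higher in BAT as groups. Directional fry did not pass these lists. Its adjusted p was 0.0618 for oxidative phosphorylation and 0.0663 for the tricarboxylic acid cycle. For fatty acid oxidation it was 0.0707, and for branched-chain amino acid breakdown 0.138. Mixed fry passed all of them, with adjusted p from 0.0219 to 0.031. Of 69 nuclear-encoded genes of oxidative phosphorylation, 31 were higher and 0 lower, or 64 and 1 with the adjustment over the list alone (median log2 difference 1.00, camera adjusted p = 2.49e-28; adjusted p = 0.281 with an estimated correlation). Uqcrb of complex III rose by 1.57 ± 0.18, Ndufa5 of complex I by 1.49 ± 0.22, and cytochrome c (Cycs) by 1.40 ± 0.17. Of 24 tricarboxylic acid cycle genes, 11 were higher and 0 lower, or 22 and 0 over the list alone (median 1.25, camera adjusted p = 2.21e-16; adjusted p = 0.281 with an estimated correlation). Among them were Sucla2 (2.16), Idh3a (1.79) and Idh2 (1.39). Of 27 genes of fatty acid oxidation, 11 were higher and 0 lower, or 15 and 0 over the list alone (median 0.80, camera adjusted p = 9.49e-12; adjusted p = 0.352 with an estimated correlation). Both subunits of the mitochondrial trifunctional protein, Hadhb (2.04) and Hadha (1.80), were among these, as was the thiolase gene Acaa2 (2.00). Of 19 genes of branched-chain amino acid breakdown, 3 were higher and 0 lower, or 11 and 0 over the list alone (median 0.70, camera adjusted p = 5.28e-06; adjusted p = 0.504 with an estimated correlation). In lipid synthesis, 1 of 19 genes passed, the elongase gene Elovl6 (0.97, adjusted p = 0.0372), also 1 over the list alone, and the list did not (camera adjusted p = 0.458; median -0.10, mean 0.09).

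Genes lower in BAT than in eWAT included secreted, matrix and immune genes. Retn, which encodes the adipokine resistin, averaged 15.07 ± 5.18 CPM in BAT and 249.6 ± 51.2 in eWAT, a log2 difference of -4.08 ± 0.30 (adjusted p = 0.00903). The small proteoglycan decorin (Dcn) averaged 147.4 ± 16.5 against 1888 ± 308 CPM and fell by 3.68 ± 0.25 (adjusted p = 0.00657), and dermatopontin (Dpt) fell by 3.87 ± 0.26 (adjusted p = 0.00657). The acute phase gene Saa3 averaged 5.248 ± 3.64 against 2738 ± 2036 CPM (-8.93 ± 0.86, adjusted p = 0.0133). Cyp2e1, a cytochrome P450 gene, had 1 count in BAT and 2358 in eWAT (ratio 2219, counting interval 397.8 to 87671; adjusted p = 0.0313). The collagen gene Col6a5 had a ratio of 426.2 (145.5 to 2069) and Gdpd2 of 104.9 (28.7 to 871.7). These intervals hold counting noise only: the eWAT libraries averaged 329.6 ± 393 CPM for Cyp2e1 and 189.4 ± 217.7 for Col6a5. Each passed under 9 of 16 alternatives, with adjusted p up to 0.264 and 0.274. The muscarinic receptor gene Chrm3 was at least 28.1-fold lower in BAT, the Wnt agonist gene Rspo1 at least 20.8-fold, Calca, which encodes calcitonin and its related peptide, at least 17.0-fold, and Ms4a8a at least 15.5-fold. The cytokine gene Il33 (-6.11, and from -7.40 to -5.07 with a library left out) and the adhesion gene Chl1 (-6.09, -6.99 to -4.77) complete the 10 largest, with adjusted p from 0.0133 to 0.0417. In mm9, Retn (NM_001204959) lies on chromosome 8 from 3655770 to 3659818, Saa3 (NM_011315) on chromosome 7 from 53967368 to 53971046, and Cyp2e1 (NM_021282) on chromosome 7 from 147949731 to 147960876.

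Some regulators of regional identity differed between BAT and eWAT. Wt1, a transcription factor gene of visceral fat and mesothelium, averaged 1.036 ± 0.925 CPM in BAT and 29 ± 0.82 in eWAT (-4.58 ± 0.63, adjusted p = 0.023). It lies on mm9 chromosome 2 from 104966686 to 105013771 (NM_144783). Tcf21, a regulator of visceral mesenchyme, averaged 0.423 ± 0.598 against 31.78 ± 25.2 CPM (-5.84 ± 1.05, adjusted p = 0.0361), and Gata6 fell by 2.11. The difference for Tcf21 ran from -9.889 to -4.656 over all alternatives. Of 25 tested patterning regulators outside the Hox clusters, 2 were higher and 4 lower in BAT, or 3 and 6 over the list alone, with a median of -0.18 (camera adjusted p = 0.57). Of 10 Hox genes of paralogue groups 6 to 13, 0 were higher and 2 lower, or 0 and 3 over the list alone (median -1.44, camera adjusted p = 0.0078; adjusted p = 0.281 with an estimated correlation). Those called were Hoxc8 (12.67 ± 0.613 against 68.34 ± 17 CPM, adjusted p = 0.0147) and Hoxc9 (1.484 ± 0.605 against 9.068 ± 0.354 CPM, adjusted p = 0.0284). Hoxc10 had 0 counts in BAT and 2 in eWAT (adjusted p = 0.374). None of 10 Hox genes of groups 1 to 5 passed (camera adjusted p = 0.458).

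Markers of other cell types moved with this contrast. All 18 tested macrophage markers were lower in BAT than in eWAT with the adjustment over the list alone, and 8 over all genes (median -3.55, camera adjusted p = 1.32e-15; adjusted p = 0.281 with an estimated correlation). Among the 8 were the lysosomal gene Cd68 (-4.07, and from -5.55 to -3.51 with a library left out), the integrin gene Itgam (-3.77, -5.03 to -3.23) and the endotoxin receptor gene Cd14 (-2.82). Complement genes moved the same way, with 11 of 13 lower, or 12 over the list alone (median -2.90, camera adjusted p = 4.35e-23; adjusted p = 0.209 with an estimated correlation). They included C3 (50.11 ± 13.5 against 1489 ± 906 CPM, -4.90 ± 0.55). So did cytokines and acute phase genes (3 of 15 lower, 6 over the list alone; median -1.89, camera adjusted p = 6.02e-09; adjusted p = 0.281 with an estimated correlation). Interferon response genes did as well (2 of 16 lower, also 2 over the list alone; median -1.08, camera adjusted p = 0.000116; adjusted p = 0.557 with an estimated correlation). Of 38 matrix genes, 8 were lower and 0 higher, or 16 and 0 over the list alone (median -0.73, camera adjusted p = 4.27e-09; adjusted p = 0.281 with an estimated correlation). They included lumican (Lum, -5.14) and the type III collagen gene Col3a1 (-2.36). Preadipocyte and fibroblast markers had 6 of 19 lower, such as Pdgfra (-1.86) and Icam1 (-2.96), and 1 higher, Thy1 (1.90), or 11 and 1 over the list alone (median -1.65, camera adjusted p = 3.68e-06; adjusted p = 0.281 with an estimated correlation). White adipocyte genes had 6 of 11 lower, or 7 over the list alone (median -1.69, camera adjusted p = 3.32e-07; adjusted p = 0.209 with an estimated correlation).

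Other lists also passed camera in this contrast. The 8 skeletal muscle markers had a median of 1.69 (camera adjusted p = 0.0078; adjusted p = 0.379 with an estimated correlation). Over the list alone 6 were higher and 1 lower in BAT, but over all genes 0 were higher and 1 lower, Actn3 (-2.24). The 4 Schwann cell markers had a median of 1.19 (0.00421, and 0.281 with an estimated correlation) and 1 member called, S100b, also over the list alone. Adipokines had 2 higher, among them Nrg4 (2.41), and 4 lower, such as Igf1 (-3.67) and the adipsin gene Cfd (-3.25), or 3 and 4 over the list alone (median -0.06; camera adjusted p = 0.0376, and 0.281 with an estimated correlation). The BMP and TGF-beta pathway (median -0.52; 0.011, and 0.632 with an estimated correlation) had 1 of 27 lower, Ltbp1 (-3.37), also over the list alone. None of 28 cell cycle genes was called, with either adjustment (median -0.60; 0.0295, and 0.749 with an estimated correlation). The lists that did not pass were beige markers (camera adjusted p = 0.514), Wnt pathway (0.204), retinoid metabolism (0.93), endothelial (0.0581), smooth muscle (0.681), mesothelial (0.522) and immediate early genes (0.327). Among them the purinergic receptor gene P2rx5 (2.38), the retinoid binding protein gene Rbp7 (2.48) and the alcohol dehydrogenase gene Adh7 (3.16) were higher in BAT, and the retinaldehyde dehydrogenase gene Aldh1a1 was lower (-2.36). Smooth muscle genes (median 0.10, mean -0.10, test downward) and retinoid genes (0.04, -0.11, upward) had measures that differed in sign. In each contrast only 4 of 12 mesothelial genes were tested, so that list result does not cover the rest. The untested ones had few counts, and most of these lay in eWAT. Upk3b, for example, had 5 and 23 counts in the eWAT libraries, 0 and 1 in BAT and 0 and 0 in iWAT.

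In all, 318 genes were higher and 440 lower in BAT than in eWAT by edgeR, with 3039 of 11732 at an unadjusted p below 0.05. DESeq2 called 599 and 771, and limma voom 242 and 314. The counts varied with the library left out: without BAT replicate 1 they were 415 and 414, without BAT replicate 2 they were 4 (Cox7a1, Thy1, Tmem45b and Ucp1) and 13, without eWAT replicate 1 they were 6 and 71, and without eWAT replicate 2 they were 7 and 64. Without iWAT replicate 1 they were 49 and 145, and without iWAT replicate 2 they were 34 and 112. Ucp1, Tmem45b, Retn, Dcn and Dpt passed in this contrast under each of the 16 alternatives, those that leave out a library included.

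The contrast of BAT with iWAT asked how brown fat adipocytes differ from those of the subcutaneous depot. Ucp1 was again higher in BAT, with 1055 ± 84.5 CPM in iWAT and a log2 difference of 2.75 ± 0.36 (adjusted p = 0.0314). Rgs7, which encodes a regulator of G protein signalling, averaged 22.66 ± 6.35 CPM in BAT and 0.853 ± 0.495 in iWAT (4.66 ± 0.51, adjusted p = 0.0225). Hoxa5 averaged 38.18 ± 10.4 against 2.711 ± 0.432 CPM (3.79 ± 0.32, adjusted p = 0.0154), and Tmem45b was higher by 3.10 ± 0.19 (adjusted p = 0.011). The others of the 10 largest were the receptor kinase gene Adrbk2 (2.79), the kinesin gene Kifc3 (2.69), the mitochondrial protein gene Nipsnap1 (2.49), the peptidase gene Mme (2.09), Sucla2 (1.77) and Ebf2 (1.71), with adjusted p from 0.0249 to 0.0497. In mm9, Rgs7 (NM_011880) lies on chromosome 1 from 176989207 to 177422676 and Hoxa5 (NM_010453) on chromosome 6 from 52151753 to 52154586.

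Several brown fat anchors did not pass in this contrast by edgeR with the low-count filter and depot as the only term, whose values are given first. Cidea averaged 62.94 ± 54.9 CPM in iWAT against 756 in BAT (log2 difference 3.58 ± 0.70, adjusted p = 0.0909). Over all alternatives that difference ran from 2.895 to 4.969. Zic1 had a ratio of 21.8 (counting interval 7.097 to 108.6; adjusted p = 0.0633), and Lhx8 a difference of 1.73 ± 0.45 (adjusted p = 0.149). Prdm16 averaged 7.316 ± 3.17 CPM in BAT and 5.045 ± 0.331 in iWAT (adjusted p = 0.67), and Tbx15 averaged 40.45 ± 11.2 and 81.02 ± 7.21 (adjusted p = 0.329). Cidea and Zic1 did pass by DESeq2 and by edgeR with no filter, with lowest adjusted p of 1.06e-06 and 0.000753. Ppargc1a averaged 56.51 ± 29.2 CPM in iWAT (adjusted p = 0.449). Of 25 thermogenic genes, 2 were higher by edgeR, Ucp1 and Ebf2, and 0 lower, or 15 and 0 over the list alone (median 1.41, camera adjusted p = 1.96e-15; adjusted p = 0.151 with an estimated correlation). Oxidative phosphorylation had 0 of 69 genes called by edgeR over all genes and 51 higher over the list alone (median 0.73, camera adjusted p = 2.97e-24; adjusted p = 0.329 with an estimated correlation). For the tricarboxylic acid cycle these counts were 1 (Sucla2) and 20 of 24 (median 0.99, camera adjusted p = 3.27e-15; adjusted p = 0.326 with an estimated correlation). For fatty acid oxidation they were 1 (Hadhb) and 13 of 27 (median 0.68, camera adjusted p = 1.2e-11; adjusted p = 0.357 with an estimated correlation). Branched-chain amino acid genes had 0 and 8 of 19 (median 0.58, camera adjusted p = 6.88e-07; adjusted p = 0.448 with an estimated correlation). Brown lineage markers had 0 and 2 of 8 (median 0.39, camera adjusted p = 0.0157; adjusted p = 0.326 with an estimated correlation). DESeq2 called more members of these lists higher and 0 lower: 13 thermogenic, 24 oxidative phosphorylation, 14 tricarboxylic acid cycle, 11 fatty acid oxidation, 6 branched-chain and 1 brown lineage gene.

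Some posterior Hox genes were lower in BAT than in iWAT, and Hoxa5 of the anterior groups was higher. Hoxc10 had 0 counts in BAT and averaged 19.75 ± 2.69 CPM in iWAT, at least 48.4-fold lower (adjusted p = 0.0365; NM_010462, mm9 chromosome 15, 102797227 to 102802328). Hoxa10 had a ratio of 135.5 (counting interval 37.18 to 1124; adjusted p = 0.0235; NM_001122950, chromosome 6, 52181196 to 52190853). Hoxa9 averaged 3.2 ± 0.34 against 43.22 ± 12.5 CPM (adjusted p = 0.0162), and Hoxc9 1.484 ± 0.605 against 11.67 ± 0.505 (adjusted p = 0.0348). Of 10 genes of groups 6 to 13, 4 were lower and 0 higher, or 5 and 1 over the list alone (median -1.22, camera adjusted p = 8.42e-09; adjusted p = 0.101 with an estimated correlation). Of 10 genes of groups 1 to 5, Hoxa5 was higher, or 3 over the list alone, with 0 lower (median 1.23, camera adjusted p = 1.04e-07; adjusted p = 0.101 with an estimated correlation). Wt1 averaged 1.036 ± 0.925 CPM in BAT and 11.7 ± 6.59 in iWAT (adjusted p = 0.0911), and Shox2 3.386 ± 2.085 and 15 ± 0.468 (adjusted p = 0.12). Both passed with no filter on low counts (0.000147 and 0.00949), and Wt1 by DESeq2. Tcf21 had 4 and 2 counts (adjusted p = 0.833). Other patterning genes were lower as a list, with 2 of 25 called, Irx1 (-3.55) and Irx2 (-2.83), or 11 over the list alone (median -0.99, camera adjusted p = 3.29e-08; adjusted p = 0.151 with an estimated correlation).

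**Figure D3:**
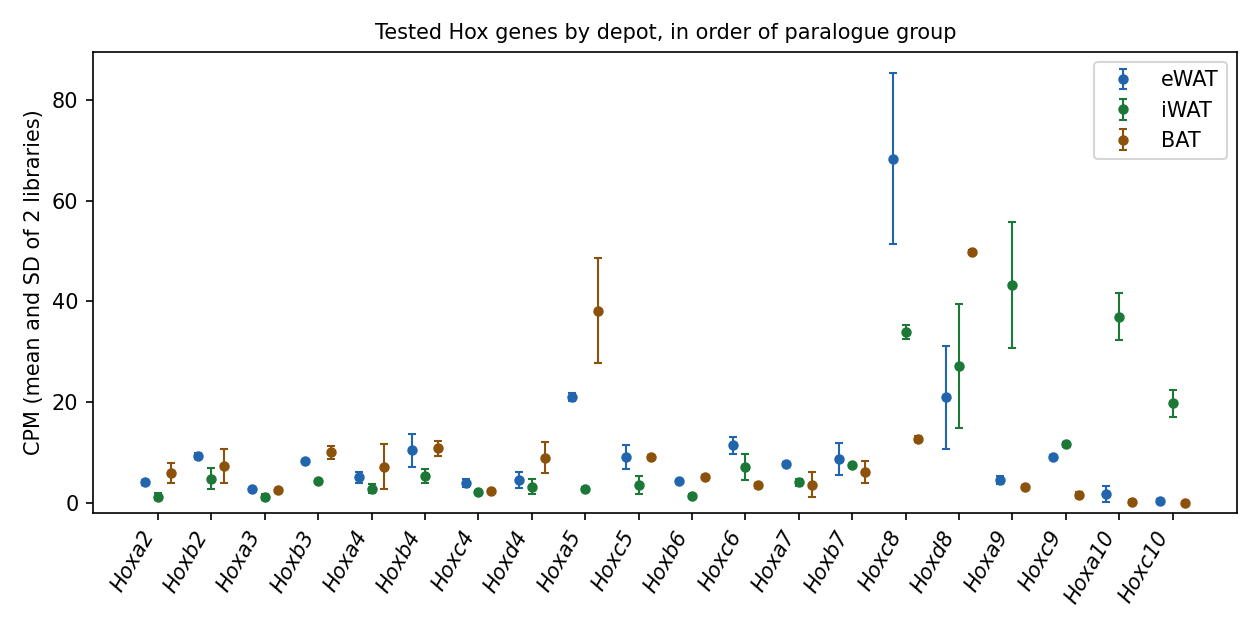
Mean CPM of the 20 tested Hox genes (y axis) in BAT, eWAT and iWAT, ordered by paralogue group along the x axis, with error bars of 1 SD over 2 libraries. Hoxa9 and Hoxc10 stand at 43.22 and 19.75 CPM in iWAT, Hoxc8 at 68.34 in eWAT, and Hoxd8 at 49.77 in BAT.

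Matrix, complement and fibroblast genes were also lower in BAT than in iWAT. The stromelysin gene Mmp3 averaged 10.03 ± 3.12 CPM in BAT and 486.1 ± 161 in iWAT (-5.63 ± 0.47, adjusted p = 0.0152), and the matrix gene Spon1 7.929 ± 2.85 against 221 ± 60.8 (-4.84 ± 0.34, adjusted p = 0.011). Of 38 matrix genes, 9 were lower and 0 higher, or 20 and 0 over the list alone (median -1.19, camera adjusted p = 2.97e-24; adjusted p = 0.101 with an estimated correlation). They included Dcn (-3.56), Col3a1 (-2.52) and the collagen VI genes Col6a1, Col6a2 and Col6a3 (-1.24, -1.46 and -2.02). Complement had 6 of 13 lower, or 11 over the list alone (median -2.87, camera adjusted p = 1.72e-24; adjusted p = 0.101 with an estimated correlation), such as C2 (-3.30), C1ra (-2.96) and Cfb (-2.87). Fibroblast markers had 4 of 19 lower, or 9 over the list alone (median -1.14, camera adjusted p = 4.81e-11; adjusted p = 0.151 with an estimated correlation), namely Ly6c1 (-4.05), Icam1 (-2.61), Pdgfra (-2.47) and Ly6a (-2.38). Of 18 macrophage markers, 15 had a negative log2 difference, but 0 passed, also over the list alone (median -0.55, camera adjusted p = 0.192). The rest of the 10 largest were Saa3 (-7.88, and from -8.93 to -7.39 with a library left out), the regenerating protein gene Reg1 (ratio 202.3, counting interval 35.94 to 8026), Il33 (-6.83, -8.11 to -5.83), Fxyd6 (-5.62), the oxysterol hydroxylase gene Cyp7b1 (-4.80) and Ifi205 (-4.73), with adjusted p from 0.011 to 0.0364. Retn (-2.57), Dpt (-3.58) and Igf1 (-2.68) were lower here too.

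White adipocyte genes had 2 of 11 lower, or 5 over the list alone (median -1.17, camera adjusted p = 1.12e-06; adjusted p = 0.101 with an estimated correlation). Cytokines had 2 of 15, or 4 (median -0.77, camera adjusted p = 1.86e-07; adjusted p = 0.326 with an estimated correlation). Adipokines had 2 of 15, or 5 (median -0.18, camera adjusted p = 0.00409; adjusted p = 0.151 with an estimated correlation). The BMP and TGF-beta list had 1 of 27 lower, the receptor gene Tgfbr2 (-1.40), or 3 lower and 1 higher over the list alone (median -0.47, camera adjusted p = 0.0101; adjusted p = 0.655 with an estimated correlation). Skeletal muscle markers had 0 of 8 called, also over the list alone (median 1.02, camera adjusted p = 0.0102; adjusted p = 0.412 with an estimated correlation). The core, lipogenic, beige, endothelial, Schwann, smooth muscle, mesothelial, cell cycle, interferon, retinoid, Wnt and immediate early lists did not pass, with camera adjusted p from 0.147 to 0.883. Beige markers (median -0.67, mean -0.22, test upward) and retinoid genes (0.17, 0.10, downward) differed in sign between measures, and the mesothelial median of 0.50 was 0.35 with genes at 0 set to their bound.

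In all, 17 genes were higher and 105 lower in BAT than in iWAT by edgeR (1951 at an unadjusted p below 0.05), against 179 and 331 by DESeq2 and 7 and 62 by limma voom. Without BAT replicate 1 the counts were 6 and 11, without eWAT replicate 1 they were 7 and 87, without eWAT replicate 2 they were 5 (Hoxa5, Kifc3, Rgs7, Sgk2 and Tmem45b) and 79, and without iWAT replicate 1 they were 0 and 4 (Cpxm1, Ifi205, Sned1 and Spon1). They were 0 and 0 without BAT replicate 2 and without iWAT replicate 2. Some folds changed little: over all alternatives Tmem45b ran from 2.966 to 3.242, Spon1 from -5.208 to -4.466 and Dcn from -3.676 to -3.434.

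The pair of BAT contrasts shared 15 genes called highest in BAT, where independent lists would share 0.461 and simulated data with no depot effect gave 0.02 on average, at most 1. Part of the excess may come from the BAT libraries that the contrasts share. The simulated data sets had only 1.46 calls each on average over all contrasts. Their overlaps therefore cannot show how far shared libraries raise the overlap of longer lists. By the smaller of the log2 differences over eWAT and iWAT, the leading genes were Rgs7 (3.52 and 4.66), Tmem45b (5.35 and 3.10), Ucp1 (6.86 and 2.75), Kifc3 (2.50 and 2.69), Adrbk2 (2.31 and 2.79), Mme (2.99 and 2.09), Nipsnap1 (1.95 and 2.49), Sucla2 (2.16 and 1.77), Ebf2 (1.82 and 1.71) and the collagen gene Col27a1 (2.46 and 1.61). Another 73 genes were lower in BAT than in both other depots, with 3.94 for independent lists and 0.08 in simulation. By edgeR with the low-count filter and depot as the only term, no gene was called highest in eWAT or in iWAT. Limma voom also called 0 and 0, but DESeq2 called 165 and 42, and 164 highest in BAT. With no filter on low counts edgeR called 322 and 79, and 219 highest in BAT. Without BAT replicate 1 the count was 5 (Nipsnap1, Tmem45b and Ucp1 of the 15, and Cib2 and Mroh6 besides). It was 2 (Tmem45b of the 15, and Sgk2 besides) without eWAT replicate 1 or without eWAT replicate 2, and 0 without BAT replicate 2 or without 1 of the iWAT replicates.

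The contrast of iWAT with eWAT asked how the white depots differ. By edgeR with the low-count filter and depot as the only term, 0 genes passed in either direction, with 1096 at an unadjusted p below 0.05 (458 higher and 638 lower in iWAT) where chance gives 586.6, and a smallest adjusted p of 0.0759. That count depends on the settings: the same test with no filter called 204 higher and 353 lower. DESeq2 called 113 higher and 188 lower in iWAT, in a test that gave 15 false calls on simulated data with no difference, and limma voom called 1, Ucp1 (log2 difference 4.10, adjusted p = 0.0345). The genes described here are DESeq2 calls, with log2 differences and adjusted p-values from DESeq2. None of them passed in the filtered edgeR fit with depot as the only term. Ucp1 was 4.11 ± 0.35 higher in iWAT (adjusted p = 3.57e-28, and 0.0759 by edgeR). Tbx15 averaged 81.02 ± 7.21 CPM in iWAT and 1.939 ± 2.08 in eWAT (5.45 ± 0.60, adjusted p = 7.66e-16; NM_009323, mm9 chromosome 3, 99057683 to 99158183). Over all alternatives its log2 difference ran from 4.557 to 7.351. Cidea was higher by 4.2 (adjusted p = 4.55e-07, and from 2.807 to 4.897 over all alternatives). Cox7a1 was higher by 1.39 and the proton channel gene Otop1 by 1.68, while Adrb3 was lower (-1.48, adjusted p = 1.14e-06). Thermogenic genes had 5 higher and 1 lower of 25 by DESeq2, or 6 and 2 by edgeR over the list alone (median 0.51, camera adjusted p = 3.98e-06; adjusted p = 0.413 with an estimated correlation). Retn was lower in iWAT, with 87.64 ± 7.25 against 249.6 ± 51.2 CPM (-1.51 ± 0.32, adjusted p = 0.000449). Prdm16 averaged 5.045 ± 0.331 CPM in iWAT and 0.608 ± 0.458 in eWAT (edgeR adjusted p = 0.181), and Lhx8 had a ratio of 24 (counting interval 3.928 to 985.3; 0.136). Both passed with no filter (0.0123 and 0.0046). Zic1 had 3 and 0 counts (0.556), and Ppargc1a and Hoxc9 had edgeR adjusted p of 0.978 and 0.936.

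Patterning genes were among those called between the white depots by DESeq2. Higher in iWAT by DESeq2 were Hoxc10 (ratio 77.3, counting interval 21.05 to 643.5), Hoxa10 (4.43), Hoxa9 (3.26), Shox2 (ratio 58.6, counting interval 15.87 to 488.9), Irx1 (3.39), Irx2 (3.03) and Twist1 (1.82), with adjusted p from 2.85e-08 to 0.000327. Lower in iWAT were Tcf21 (ratio 136.5, counting interval 37.41 to 1133; adjusted p = 2.19e-05), Hoxa5 (-2.96, adjusted p = 1.63e-06), Osr1 (-2.32) and Bmp4 (-2.74). Wt1 averaged 11.7 ± 6.59 CPM in iWAT and 29 ± 0.82 in eWAT (edgeR adjusted p = 0.447). Hox genes of groups 1 to 5 had 1 of 10 lower in iWAT by DESeq2, also over the list alone (median -0.97, camera adjusted p = 1.5e-07; adjusted p = 0.29 with an estimated correlation). Those of groups 6 to 13 had 3 of 10 higher and 0 lower by DESeq2, or 3 and 2 over the list alone (median 0.07, camera adjusted p = 0.00144; adjusted p = 0.327 with an estimated correlation). Other patterning genes had 6 higher and 2 lower of 25, or 10 and 4 over the list alone (median 0.72, camera adjusted p = 9.51e-08; adjusted p = 0.327 with an estimated correlation). The rest of the 10 largest differences by DESeq2 in favour of iWAT were Reg1, Galnt13, Nrn1, Cadm2, Mmd2, Dkk2 and Rpl39l, and in favour of eWAT Cyp2e1, C1qb, Col6a5, Shisa3, Ms4a8a, Fcna, Adra1b, Gdf6 and Lyz1.

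Macrophage markers were higher in the eWAT cultures. By DESeq2, 12 of 18 were lower in iWAT than in eWAT and 0 higher, as were all 18 by edgeR over the list alone (median -3.08, camera adjusted p = 1.23e-28; adjusted p = 0.327 with an estimated correlation). Cd68 averaged 10.5 ± 4.54 CPM in iWAT and 91.46 ± 25.2 in eWAT (-3.12, adjusted p = 2.05e-05), and Itgam 13.26 ± 8.8 and 126.4 ± 17.5 (-3.25, adjusted p = 3.09e-05). The receptor gene Csf1r differed by -2.45 (adjusted p = 0.00193). Interferon response genes also lay lower in iWAT (0 of 16 called, also over the list alone, median -0.80, camera adjusted p = 6.3e-05, and 0.688 with an estimated correlation). So did cytokines (0 of 15, also over the list alone, median -0.83, camera adjusted p = 0.00623, and 0.753 with an estimated correlation). Complement genes lay lower too (2 of 13 lower by DESeq2, 3 over the list alone, median -0.51, camera adjusted p = 0.00138, and 0.413 with an estimated correlation). Between replicates the complement genes did not follow the macrophage markers. From replicate 1 to replicate 2 the complement median changed by -0.0876 in BAT, 1.07 in eWAT and 0.128 in iWAT. The macrophage median changed by -1.83, -1.11 and -1.39. Endothelial markers lay higher in iWAT (0 of 12 called, also over the list alone, median 0.89, camera adjusted p = 3.07e-05, and 0.58 with an estimated correlation). From replicate 1 to replicate 2 their median changed by 0.949 in eWAT, -0.91 in BAT and 0.115 in iWAT. The change in eWAT is about as large as the difference between the depots. Schwann cell markers also lay higher in iWAT (1 of 4 called by DESeq2 and over the list alone, S100b, median 1.08, camera adjusted p = 0.00169, and 0.399 with an estimated correlation). Matrix genes had 4 of 38 higher in iWAT by DESeq2, also 4 over the list alone, including Col6a1 and Col6a3 (1.04 and 1.31; list median 0.34, camera adjusted p = 0.000975; adjusted p = 0.541 with an estimated correlation). The fibroblast marker Thy1 averaged 135.4 ± 5.09 CPM in iWAT and 16.18 ± 1.16 in eWAT (3.07, adjusted p = 5.79e-09), although its list did not pass (camera adjusted p = 0.38).

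Camera passed other lists here as well. Brown lineage (1.49, camera adjusted p = 1.62e-05; adjusted p = 0.327 with an estimated correlation), lipogenic (0.21, 0.00864, and 0.413 with an estimated correlation), fatty acid oxidation (0.18, 0.0331, and 0.794), oxidative phosphorylation (0.26, 1.16e-05, and 0.753) and tricarboxylic acid cycle genes (0.29, 0.00367, and 0.766) lay higher in iWAT. White adipocyte genes (-0.24, 0.0292, and 0.399) and cell cycle genes (-0.56, 0.00552, and 0.766) lay lower. By DESeq2 1 brown lineage gene, Ebf3, and 1 lipogenic gene, Elovl6 (1.25), were higher, 2 white adipocyte genes, Retn and Tcf21, were lower, and 0 members of the other 4 lists passed. Over the list alone, edgeR called 2 brown lineage and 1 lipogenic gene higher, 2 white adipocyte genes lower, and 0 in the other 4 lists. The core, beige, branched-chain, fibroblast, smooth muscle, mesothelial, skeletal muscle, retinoid, adipokine, BMP, Wnt and immediate early lists did not pass, with camera adjusted p from 0.343 to 0.991. The median, mean and test differed in sign for fibroblast (-0.29, 0.07, upward), beige (-0.07, 0.42, upward), core (-0.02, 0.02, upward), retinoid (-0.28, -0.20, upward), adipokine (-0.15, -0.07, upward) and immediate early genes (0.11, -0.04, upward). The edgeR count became 2 higher, Thy1 and Ucp1, without BAT replicate 1 or without BAT replicate 2, and 1 higher (Ngfr, 6.20) and 2 lower (Col6a5 and Cyp2e1, -6.39 and -6.77) without eWAT replicate 1.

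**Figure D4:**
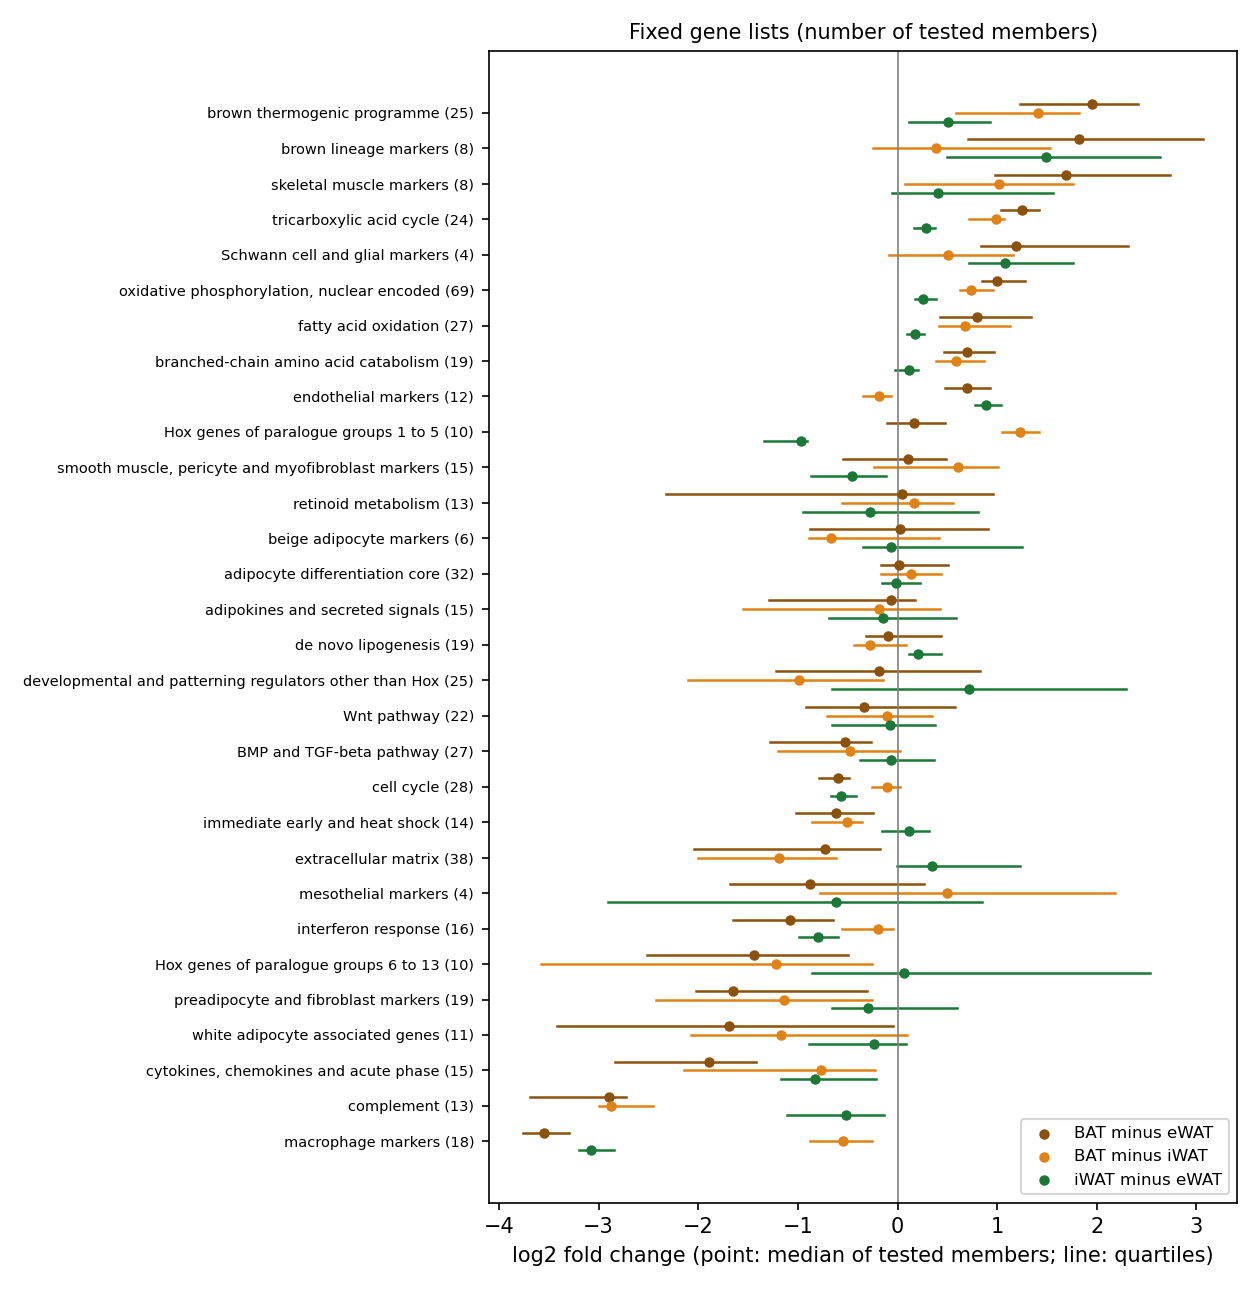
Median log2 fold change of the tested members of 30 gene lists (x axis, points) with lines from the lower to the upper quartile, for the 3 contrasts of depots. Macrophage markers have a median of -3.55 for BAT minus eWAT, -0.55 for BAT minus iWAT and -3.08 for iWAT minus eWAT, and oxidative phosphorylation 1.00, 0.73 and 0.26.

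Of the remaining cell type lists, lymphocyte, epithelial and erythroid markers had 0 tested members. Their highest counts over the 2 libraries of a depot were 15 for Lck (iWAT), 13 for Elf3 (BAT) and 21 for Epor (eWAT). Saa3, Serpina3n, Ly6a, Ly6c1, Cyp2e1, Ms4a8a, Reg1, Ifi205 and many respiratory chain genes have close paralogues or processed pseudogenes, and the handling of reads shared between them is not given in the sources used here.

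In the authors' own table, 1336 genes were higher and 1836 lower in BAT than in eWAT at an adjusted p below 0.05, 590 and 1082 in BAT than in iWAT, and 660 and 1070 in iWAT than in eWAT. All 758 and 122 genes called here in the contrasts of BAT with eWAT and with iWAT were past that threshold in the authors' table with the same direction. Across the tested genes the log2 fold changes correlated at 0.9983, 0.9974 and 0.9988 in that order of contrasts. The authors' table covers 20295 genes, against 11732 tested here, so the counts of calls are not like for like. The p-values differ gene by gene as well. For Ucp1 in iWAT over eWAT the authors' adjusted p was 2.14e-114, against 0.0759 by edgeR here, at nearly the same log2 fold change. It describes the same libraries, so the overlap and the correlations are not independent evidence. For Ucp1, the authors' log2 fold changes were 6.79 over eWAT and 2.64 over iWAT in BAT, and 4.09 for iWAT over eWAT.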

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

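The alternative without Scd1 was the only one chosen after the data were seen, and the one that sums genes sharing a symbol was not run because no symbol repeats. In the following, counts for a depot pair come as higher and lower in the first depot, in the order BAT with eWAT, BAT with iWAT and iWAT with eWAT, and then as genes highest in BAT, eWAT and iWAT. As reported they were 318 and 440, 17 and 105, 0 and 0, and 15, 0 and 0. Median-of-ratios scaling, upper-quartile scaling, the stricter filter, the 2-fold minimum and the fit without Scd1 kept each of these counts within 1.5 times its reported value, and the scalings moved the median log2 difference of all genes by from -0.0148 to 0.00501, and the fit without Scd1 by from -0.0199 to 0.0175. Among the 122 called gene results named by the rule, none reversed under any of the 16 alternatives: 121 stayed past the threshold with median-of-ratios scaling, 120 with upper-quartile scaling, 122 with no filter or the stricter filter, 121 with DESeq2, 93 with limma voom and 121 without Scd1. Depth limits the folds of genes near 3 counts (0.634 to 1.15 CPM in a library), which are known only as bounds or within wide counting intervals.

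With no filter on low counts the numbers rose to 769 and 1168, 249 and 531, 204 and 353, and 219, 322 and 79. DESeq2 gave 599 and 771, 179 and 331, 113 and 188, and 164, 165 and 42. Limma voom gave 7 and 62 for BAT with iWAT, 1 gene higher in iWAT than in eWAT (Ucp1, adjusted p = 0.0345, where its alternatives ran from 3.57e-28 to 0.312) and 6 genes highest in BAT. For these settings the cause was not tested. An adjusted p below 0.01 left 2 genes higher in BAT than in eWAT (Tmem45b and Ucp1) and 12 lower, 0 and 0 for BAT with iWAT, and 0 highest in BAT, as a stricter threshold must leave fewer, and 6 of the 122 gene results. In a fit of only the 2 depots compared, which has fewer libraries to estimate the spread, the counts were 40 and 116 for BAT with eWAT and 7 higher in BAT than in iWAT, but 2 genes (Ucp1 and Thy1) were higher in iWAT than in eWAT, and 67 of 121 gene results passed. No list passed camera with an estimated correlation in any contrast (0, 0 and 0, against 19, 17 and 18 at the preset one). Directional fry, which asks another question, called 8, 8 and 2 lists, and its mixed form 24, 16 and 16.

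Leaving out each library in turn leaves a depot with a lone sample, which is assumed to vary like the others, and fewer libraries to estimate the spread. The counts then ran from 4 to 415 for genes higher in BAT than in eWAT and from 13 to 414 for those lower, from 0 to 7 for genes higher in BAT than in iWAT and from 0 to 87 for those lower. They ran from 0 to 2 for genes higher in iWAT than in eWAT, from 0 to 2 for those lower, from 0 to 5 for genes highest in BAT, from 0 to 2 for those highest in eWAT and from 0 to 1 for those highest in iWAT. Lists past camera ran from 17 to 21, from 15 to 22 and from 15 to 19. Of the 122 called gene results, 75 passed without BAT replicate 1, 8 without BAT replicate 2, 56 and 49 without eWAT replicates 1 and 2, and 43 and 35 without iWAT replicates 1 and 2. Some uncalled anchors changed sign with a library left out, and none of the 6 values that did so passed the test. Adipoq in BAT minus eWAT became 0.20 without BAT replicate 1 and 0.38 without eWAT replicate 2, in a range from -0.40 to 0.38. In BAT minus iWAT it became -0.042 without BAT replicate 2 (range -0.042 to 0.52), and in iWAT minus eWAT 0.12 without eWAT replicate 2 (range -0.66 to 0.12). Ppargc1a in iWAT minus eWAT became -0.15 without iWAT replicate 2 (range -0.15 to 1.10). The fitted value for Tcf21 in BAT minus iWAT was -3.05 without BAT replicate 1 (range -3.05 to 4.10). Neither its size nor its sign has meaning, as the gene had 4 and 0 counts in the BAT libraries and 2 and 0 in those of iWAT.

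The libraries share a replicate number across depots, but the labels state no shared animal, litter or day, and only 2 such pairs exist per comparison. Across 11732 genes the deviations of replicate 1 from its depot mean correlated at 0.412 between BAT and eWAT, 0.448 between BAT and iWAT and 0.556 between eWAT and iWAT. A replicate block, which is a term for that number, gave 1276 and 1504, 534 and 691, 195 and 368, and 493, 344 and 81, with all the reported calls kept, and called 234 genes higher and 560 lower in replicate 2 than in replicate 1. With it, camera also called macrophage markers and immediate early genes lower in BAT than in iWAT (adjusted p = 0.0386 and 0.00782, against 0.192 and 0.149 without). Smooth muscle markers were called lower in iWAT than in eWAT (0.0254 against 0.343), and no list lost its call. Of the anchors that the depot-only fit did not call, Pparg (adjusted p = 0.00347) and Ppargc1a (0.00234) passed in BAT minus eWAT, and Cidea, Zic1, Wt1, Shox2, Lhx8 (0.0391), Pparg (0.0388) and Ppargc1a (0.0191) in BAT minus iWAT. In iWAT minus eWAT they were Ucp1, Cidea, Lhx8, Tbx15, Shox2, Hoxc10, Tcf21 and Retn. In simulated data, a shared difference between replicates with an SD of 1 log2 unit was added to the genes. It came on top of the spread estimated without a block. The fit without the block then recovered 0% of 200 changed genes and the fit with it 53.5%, with 14 false calls. The size of that effect was not fitted to these data, so these shares do not measure the loss of power here. As no label says that equal numbers belong together, the depot-only fit stays the one reported.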

Other observations

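The tests of a lower or higher share of adipocytes and the second macrophage list were chosen only after the results they measure were seen, and the other tests of this part before. Some gene groups told the replicates apart in every depot. The adipocyte differentiation core was higher in replicate 2 than in replicate 1, with median log2 differences of 0.48 in BAT, 0.44 in eWAT and 0.13 in iWAT. Cell cycle genes were lower in replicate 2, with medians of -1.30, -1.33 and -0.85, as were macrophage markers (-1.83, -1.11 and -1.39), smooth muscle and pericyte markers (-2.39, -0.53 and -1.26), immediate early genes (-0.92, -0.92 and -0.67) and matrix genes (-0.54, -0.43 and -0.46).

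The macrophage genes were not evenly abundant. Lyz2, the lysozyme gene of myeloid cells, averaged 2538 ± 1548 CPM (SD, n = 2) in eWAT, 287.9 ± 239 in iWAT and 192.1 ± 185 in BAT. The next most abundant were Gpnmb (702.7 ± 46, 232.3 ± 71 and 124 ± 7.22 CPM) and the elastase gene Mmp12 (446.5 ± 193, 75.04 ± 35.7 and 23.12 ± 18.1). The scavenger receptor gene Marco averaged 163 ± 142, 14.11 ± 17.5 and 4.906 ± 5.32 CPM.

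Libraries with the same replicate number deviated together in the 3 depots. Against sequencing depth as the whole cause, the lowest correlation of deviations was still 0.397 after every library was thinned to 2889038 counts, and against a gene length bias it was 0.415 after the trend on length was removed. A different degree of adipogenic differentiation is a candidate explanation: the core median was shifted the same way in each depot and outside the 95% range of expression-matched random lists, the smallest shift being 0.134 in iWAT (range -0.129 to 0.106). A shared day or operator stays open and was not tested, since the labels give none.

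Macrophage markers were higher in the eWAT than in the iWAT cultures. A lower share of adipocytes in eWAT as the whole cause would raise markers of other cell types alike. The endothelial median, however, lay 3.97 above the macrophage median (0.89 against -3.08). The permutation p was 2e-05 with 100000 resamples, smallest possible 1e-05. It was computed over genes that are not independent replicates, with both medians already known, so it does not measure the spread between cultures. From replicate 1 to replicate 2 in eWAT, the endothelial median changed by 0.949 and the macrophage median by -1.11. More macrophages among the eWAT cells may account for the pattern. A second list of 49 macrophage genes had 43 tested members outside the first list, none of them in another list. Their median for iWAT minus eWAT was -2.85, and 42 of the 43 were higher in eWAT, Ctsk (0.44) being the exception. By DESeq2, 24 were past the threshold. That list was put together with the first list's median known but its own values unseen, and 12, 17 and 39 of its members averaged at least 5 CPM in BAT, iWAT and eWAT, so some are expressed in all cultures. A change of state in the same number of macrophages, and the depot itself, stay open and untested.

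Respiratory chain genes were higher in the BAT than in the eWAT cultures. A higher share of adipocytes in BAT as the whole cause would raise the differentiation core as much. The respiratory chain median, however, lay 0.991 above the core median (1.00 against 0.01). The permutation p was 1e-05, the smallest that 100000 resamples can give. It was computed over genes that are not independent replicates, with both medians already known, so it does not measure the spread between cultures. Against a gene length bias, the median was 0.887 after the trend on length was removed, although the members are short (median counted length 692 against 2855 bases for all tested genes). From replicate 1 to replicate 2 the respiratory chain median rose by 0.512 in BAT, 0.184 in eWAT and 0.0201 in iWAT. The core median rose by 0.477, 0.438 and 0.134, so in BAT these lists shifted alike between replicates. Reads shared with processed pseudogenes were not tested. A depot difference in mitochondrial gene expression may account for the pattern and stays a hypothesis, found and tested on the same data.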
